A study of Caenorhabditis elegans with 30 samples.

How the data were processed

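The series holds 30 libraries of polyadenylated RNA from starved L1 larvae of 2 strains at 5 times of arrest, with 3 biological replicates in each of the 10 groups, per the labels. Per the labels' protocols, RNA was extracted with TRIzol, 50 ng of total RNA went into each NEBNext Ultra II library, and ERCC spike-in was added in proportion to total RNA, so that the spike-in does not measure RNA per larva. The authors' text sheet states that 50 bp paired-end reads were aligned with bowtie 1.2.2, an aligner that does not split reads over introns, to the WS273 genome with the 92 ERCC sequences, with settings that drop reads with more than 2 alignments and report 1 of them otherwise. Reads were counted with HTSeq 0.11.2, per the submitters' processing notes; the settings are not stated, so use of strand is unknown, and reads of overlapping, antisense or near-identical genes could be shared. Between 35.3% and 40.7% of reads in a library were not aligned.

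The deposited counts are raw counts per gene, ERCC control and HTSeq category. In each of the 30 libraries the counts in the sample's own file equalled those in the series table. The deposited CPM values were computed by the authors for 14928 genes; tested on the file, they are counts scaled to the protein-coding total of the library, within 0.068%, with no further scaling factor. The authors' edgeR 3.24.4 table gives log2 fold changes of irld over N2 per time, a mean log2 CPM, the F statistic (a score), the p-value and the FDR of a quasi-likelihood test on genes with CPM above 1 in at least 3 libraries, per the file headers and text sheet. There, 0 genes had an FDR under 0.05, 148 had p under 0.05 and the lowest p was 0.00147. Its log2 fold changes and those computed here had Pearson's r of 0.999 to 1.00 at each time over 14683 shared genes.

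Everything else was computed here from the deposited counts, with Python 3.11.15 and R 4.3.3. Of 46911 worm genes, 44053 (93.9%) were found in the symbol table. Coordinates are those of WBcel235 in the Ensembl 115 annotation. edgeR 4.0.16 was used with TMM scaling (factors 0.781 to 1.24), filterByExpr by group, which kept 15508 genes, and robust quasi-likelihood F-tests with 1 coefficient per group over all 30 libraries. Adjusted p values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. The biological coefficient of variation was 0.256. Total counts of 7563687 to 19815884 per library set the depth, and intervals are at 95%. Replicates of a group differed by a chi-square of 8.07 to 104 per gene, so none was a copy of another. The first principal component held 57.6% of the variance and followed time.

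Tests were the strain difference at each time, its mean over 5 times, its change with time (4 degrees of freedom), the difference between strains in the change from 6 to 72 h, each later time against 6 h within each strain, and all times within each strain (4 degrees of freedom). The tests, alternatives, gene lists and rule for named genes were fixed before the data were examined. The rule names irld-39, irld-52, daf-16, daf-2, daf-28, ins-7, sod-3, mtl-1, hsp-12.6, dod-3 and icl-1 in any case. Among genes with a public name and a mean CPM of at least 2, it adds the 10 smallest p of the interaction, the 10 largest called rises and falls in N2 from 6 to 72 h with no overlap between the 3 and 3 libraries, and the 5 largest of each in irld. For strain comparisons it would name the largest called changes, of which there were 0. For each list described it takes up to 4 members with the smallest p.

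Of 37 gene lists, 36 with at least 5 tested members were compared with the other genes by camera in limma 3.58.1, with a preset correlation of 0.01, over 9 comparisons (324 tests adjusted together). The list of genes of the mitochondrial genome was matched by its 12 protein-coding genes in the annotation. Camera was repeated with an estimated correlation, and fry and an exact permutation of strain labels within time were run as further tests. The lists cover DAF-16 targets, insulin signalling, receptor L-domain genes, stress and detoxification, lipid and carbohydrate metabolism, mitochondria, translation, protein turnover, cuticle and molting, cell cycle, hormone and nutrient signals, immunity, receptors, neuropeptides, histones, tissues, and sperm, adult, embryo and germline genes.

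The steps were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed at each of 1.25-, 1.5-, 2- and 4-fold. The changed genes were drawn from those with a mean CPM of at least 2, and all were changed at once. Recovery can differ for lower genes or where fewer genes change. For the strain mean (15305 genes), 34%, 64%, 92% and 98% were recovered and 11 unchanged genes were called. For irld against N2 at 6 h (15305 genes), 0%, 10%, 52% and 92% were recovered with 8 unchanged genes called, and for N2 at 72 h against 6 h (15151 genes) 0%, 6%, 44% and 80% with 0. With no list changed, 0 of 216 list tests were called by either correlation. With an 80-gene list raised 1.25-fold, it was called in 6 of 6 strain comparisons by both. Genes were drawn independently of each other in these simulations. The list results there do not show how either correlation setting behaves where genes move together, as in the real libraries.

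Alternatives were DESeq2 1.42.0, limma-voom, relative log expression, upper quartile, library size alone and ERCC scaling, no filter or a CPM of at least 1 in at least 3 libraries, the replicate number as a block, the compared groups alone, and each library or replicate number left out. Added after the data had been seen were protein-coding genes alone, leaving out the irld 6 h library numbered 1 with the N2 24 h library numbered 2 (both away from their group on the first component), the permutation of lists, and the mitochondrial and ribosomal RNA shares, with every alternative for shares of counts. The irld 12 h library numbered 1 and the irld 48 h library numbered 3 also stood apart on the first component, but were not left out together with these 2. A further test in the authors' text sheet that uses their own list of DAF-16 targets was not repeated, since its gene list is not among the files.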

Results

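Polyadenylated RNA was sequenced from Caenorhabditis elegans larvae that hatched without food and stayed in starvation arrest at the L1 stage. The wild-type strain N2 was compared with a double mutant of irld-39 (allele duk1) and irld-52 (allele duk17), called irld here. Larvae were collected at 6, 12, 24, 48 and 72 h of arrest, which were 18, 24, 36, 60 and 84 h after bleaching. Each of the 10 groups of strain and time held 3 biological replicates, which gave 30 libraries. Between 7563687 and 19815884 reads per library were counted to worm genes, with a median of 9650171. Of 46911 worm genes in the files, 15508 had enough counts to be tested. Levels are TMM-scaled CPM, given as mean ± SD with n = 3 libraries, and log2 differences are given with their SE.

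The mutated genes were read first. Both belong to the family of receptor L-domain genes, whose proteins resemble the ligand-binding part of the insulin receptor. irld-39 (WBGene00010415, IV 16233148 to 16236555) had 30 counts summed over the 15 irld libraries, with 0 to 6 per library, and 38 over the 15 N2 libraries, with 0 to 8. It was too low to be tested. irld-52 (WBGene00012043, V 15779679 to 15781247) had 59 counts in irld, with 1 to 12 per library, and 82 in N2, with 0 to 23. Its log2 difference, irld less N2, averaged over the 5 times was -0.08 ± 0.49 (edgeR adjusted p = 0.999). A loss of either transcript was not detectable at this depth, and the labels do not say what the alleles remove, so these counts do not test the strain labels.

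The strain comparison asked whether the mutant's transcriptome differed from that of N2 during arrest. Genes of the insulin and DAF-16 pathway lay close together in both strains. Averaged over the 5 times, irld less N2 was 0.10 ± 0.08 for daf-16, the FOXO transcription factor of this pathway, and 0.09 ± 0.09 for daf-2, the insulin/IGF receptor. For genes known to rise with DAF-16 activity it was -0.12 ± 0.15 for sod-3, a mitochondrial superoxide dismutase, -0.09 ± 0.14 for mtl-1, a metallothionein, -0.02 ± 0.19 for hsp-12.6, a small heat-shock protein, and -0.05 ± 0.13 for dod-3. It was -0.07 ± 0.35 for icl-1, the glyoxylate cycle enzyme, and 0.07 ± 0.30 for daf-28, an insulin-like peptide. ins-7, another insulin-like peptide, had 35 counts summed over irld and 29 over N2 and was not tested. Of the 37 tested members of the DAF-16-activated list, edgeR called 0 over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05, and the mean of the fitted log2 differences was -0.0025 (camera adjusted p = 0.414). From library means relative to other genes it was -0.0505 (exact permutation within time, two-sided, unadjusted p = 0.457). These 4 were the catalase genes ctl-3 (-0.27 ± 0.11), ctl-2 (-0.29 ± 0.12) and ctl-1 (-0.25 ± 0.11), adjacent copies whose reads could be shared, and the small heat-shock gene sip-1 (-0.64 ± 0.30).

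No gene passed an adjusted p of 0.05 for the strain mean: edgeR called 0 of 15508 genes, with 837 at an unadjusted p under 0.05 and a lowest adjusted p of 0.916. DESeq2 and limma-voom also called 0. For the 11771 genes with a mean CPM of at least 2, the median 95% interval reached 0.22 log2 units to either side, and for 11401 of them (96.9%) it lay within a 2-fold change. In simulated libraries this comparison recovered 92% of genes changed 2-fold and 34% of those changed 1.25-fold. Scaling on the ERCC spike-in gave 1 call, leaving out the libraries numbered 1 gave 7 and leaving out those numbered 3 gave 3.

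Each time was also compared alone. edgeR called 0 genes at 6, 12, 24, 48 and 72 h, with 171, 229, 345, 427 and 446 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 at each. At a single time the interval lay within 2-fold for 75.7% to 80.5% of the 11771 genes, and the simulated comparison at 6 h recovered 52% of genes changed 2-fold. At 24 h, ERCC scaling and leaving out the libraries numbered 1 each gave 1 call. A strain difference that changed with time was tested with 4 degrees of freedom. edgeR called 0 genes, with 0.767% of the tested genes at an unadjusted p under 0.05, DESeq2 and limma-voom called 0 and ERCC scaling gave 1. The 10 smallest p among genes with a public name and a mean CPM of at least 2 included those of dyf-3, a gene of sensory cilia, pvf-1, a growth factor gene, npr-10, a neuropeptide receptor gene, and gpdh-1, a glycerol-3-phosphate dehydrogenase gene. The others were pqn-72, doxa-1, smg-5, nhr-179, ags-3 and sru-40, and the edgeR adjusted p was 1.00 for all 10. dyf-3 went from 2.37 ± 0.41 CPM at 6 h to 7.81 ± 0.31 at 72 h in N2 and from 3.81 ± 0.55 to 4.83 ± 0.77 in irld. The change from 6 to 72 h did not differ between strains for any gene by edgeR (0 calls, 303 at an unadjusted p under 0.05), DESeq2 (0) or limma-voom (0). It was less precise than the strain mean or a single time, with a median 95% interval of 0.69 log2 units to either side and an interval within 2-fold for 57.2% of the 11771 genes. With no strain difference, unadjusted p values would lie under 0.05 for about that fraction of genes. The share was 5.4% for the strain mean, but 1.1% to 2.88% at single times and 1.95% for the difference of changes. These tests may thus be conservative, and low counts do not show that the strains were alike.

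Gene lists fixed before the data were examined were compared between strains with camera. With a preset correlation between genes, 39 of the 56 called tests, of 324 in all, were strain comparisons. They included cytosolic ribosomal protein genes, whose mean log2 difference relative to other genes was 0.15 at 6 h (adjusted p = 5.33e-13) and 0.26 at 12 h (adjusted p = 2.29e-29), and the 12 protein-coding genes of the mitochondrial genome, at 0.37 at 72 h (adjusted p = 6.20e-10). With an estimated correlation the adjusted p was 0.978, 0.797 and 0.611. None of the 324 tests was called with an estimated correlation, and none of the strain tests by fry. The estimated correlation also left uncalled the rise of ribosomal protein genes over time in N2, given below. Its lack of a call therefore decides nothing between the strains. Without the libraries numbered 1 the ribosomal difference at 6 h was -0.13. When the strain labels were exchanged within each time, 90 of 100 splits gave 39 or more called strain tests. These splits did not keep 1 library of each replicate number per group, as the real labels do, which could raise their counts. An exact permutation test of each list's mean between strains gave a lowest adjusted p of 0.936 over 72 tests. The smallest unadjusted p there were 0.015 for the molting list, in the difference between the changes from 6 to 72 h, and 0.0490 for cuticle collagens, in the strain mean. For the difference of changes, 400 splits cannot give a p small enough for a single list to pass that adjustment.

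The transcriptome changed widely between 6 h and the later times of arrest. All libraries came from starved larvae, so effects of starvation cannot be told apart from those of time since hatching. In N2, 963 genes differed from 6 h at 12 h (412 higher and 551 lower), 5296 at 24 h (2461 and 2835), 7070 at 48 h (3100 and 3970) and 7919 at 72 h (3588 and 4331). Of those at 72 h, 2152 were at least 2-fold higher and 3083 at least 2-fold lower. The test over all times with 4 degrees of freedom called 7686 genes. The count at 12 h depended on single libraries. It was 391 or 618 without the N2 6 h library numbered 2 or 3, and 535, 637 or 450 without the N2 12 h library numbered 1, 2 or 3. Without all libraries numbered 2, 1 gene was called at 12 h. The 12 h count was higher with the replicate number as a block and with the compared groups fitted alone, as given below.

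**Figure D1:**
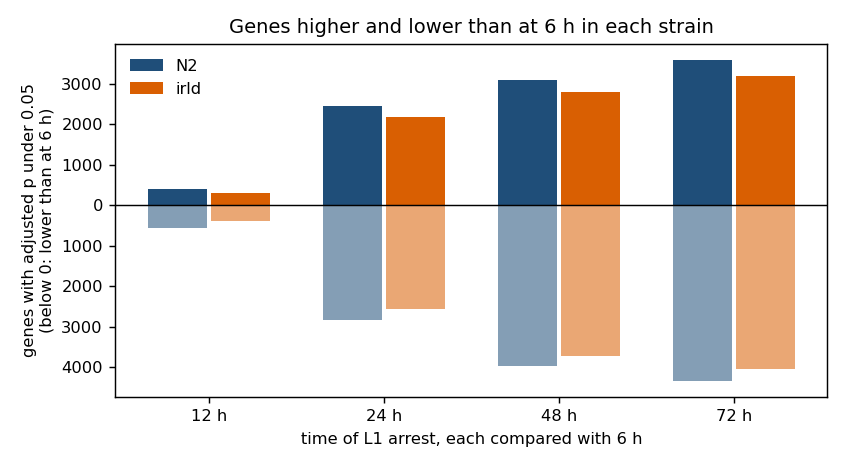
Number of genes with an edgeR adjusted p under 0.05 against 6 h (vertical axis) at each later time of arrest (horizontal axis) in N2 (blue) and irld (orange), 3 libraries per group. Dark bars above 0 count genes higher than at 6 h and pale bars below 0 count lower genes, from 963 genes in N2 at 12 h to 7919 at 72 h.

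The direction of calls depended on scaling. With the main scaling the median gene moved by -0.11 in N2 and -0.13 in irld from 6 to 72 h. In N2 the share of higher calls was 42.8%, 46.5%, 43.8% and 45.3% at 12, 24, 48 and 72 h. Upper quartile scaling gave 58.2%, 56.8%, 54.3% and 50.9%. Library size alone gave 39.7%, 27.3%, 22.6% and 21.1%, with the median gene at -0.63 at 72 h. ERCC scaling gave 0 calls at 12 h, then 0.89%, 1.43% and 9.13% of 2134, 3213 and 1873 calls, with the median gene at -0.57 at 72 h. The changes described next are relative to the other genes of the same libraries.

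Genes known to follow DAF-16 activity took different courses in N2. hsp-12.6 (IV 9446229 to 9447228) rose from 4.41 ± 1.92 CPM at 6 h to 196 ± 46 at 24 h and 258 ± 38 at 72 h (log2 5.90 ± 0.52, edgeR adjusted p = 3.25e-09). sod-3 (X 17092753 to 17094306), which opposite-strand genes overlap, rose from 4.33 ± 1.05 to 13.8 ± 2.4 CPM at 24 h (log2 1.68 ± 0.33) and stood at 4.34 ± 1.65 at 72 h (0.02 ± 0.34). In irld sod-3 rose by 1.99 ± 0.33 at 24 h and lay at -0.06 ± 0.35 at 72 h. daf-16 (I 10750498 to 10776703) rose by 0.89 ± 0.19, daf-2 (III 2994514 to 3040846) by 1.15 ± 0.21 and mtl-1 by 1.74 ± 0.33 from 6 to 72 h in N2. In irld the log2 changes were 0.92 ± 0.19 for daf-16, 0.97 ± 0.21 for daf-2 and 1.08 ± 0.32 for mtl-1, but -0.67, -0.62 and -0.89 under ERCC scaling, where they lay 0.91, 0.96 and 0.69 above the median gene. dod-3 fell by 1.27 ± 0.30 in N2 and by 1.63 ± 0.30 in irld. icl-1 (V 724332 to 728004) fell from 715 ± 91 to 40.6 ± 17 CPM in N2 (log2 -4.14 ± 0.89). daf-28 was not called (1.24 ± 0.68 in N2).

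**Figure D2:**
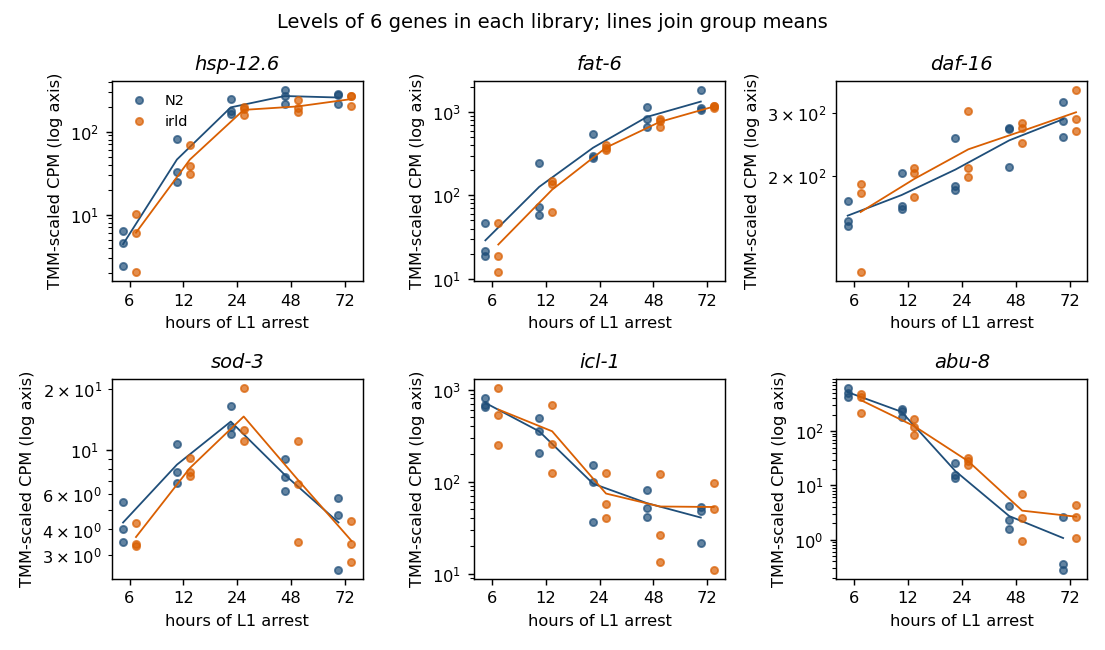
TMM-scaled CPM on log axes (vertical) of hsp-12.6, fat-6, daf-16, sod-3, icl-1 and abu-8 at each time of arrest (horizontal) in N2 (blue) and irld (orange). Points are the 3 libraries of each group and lines join group means; hsp-12.6 went from 4.41 to 258 CPM in N2 between 6 and 72 h, and sod-3 peaked at 24 h.

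Besides hsp-12.6, the 10 largest rises from 6 to 72 h in N2 were as follows. fat-6 (IV 11913692 to 11915687), a stearoyl-CoA desaturase gene, rose from 28.9 ± 14.9 to 1341 ± 434 CPM (log2 5.54 ± 0.59, edgeR adjusted p = 7.37e-08). Cuticle collagen genes among the 10 largest rises were col-50 (6.72 ± 0.69), dpy-5 (5.67 ± 1.25), col-181 (5.55 ± 0.43) and col-138, which had 2 counts summed over the 6 h libraries and 168 at 72 h. nspc-10 (6.17 ± 0.64) and nspc-9 (5.71 ± 0.57), neighbouring copies of a nematode-specific peptide family whose reads could be shared, and dach-1 (5.37 ± 0.69) were also there. The chemoreceptor gene sre-12 had 3 counts at 6 h and 92 at 72 h. The largest falls were those of abu-8 (V 5192995 to 5194608), from 523 ± 100 to 1.08 ± 1.30 CPM (-8.86 ± 0.70), and grl-21, a ground-like gene, from 498 ± 130 to 1.24 ± 1.85 CPM (-8.73 ± 1.07). They were followed by abu-10 (-8.54 ± 0.70), idpp-12 (-8.15 ± 0.82), tag-297 (-8.0 ± 0.74), nspb-12 (-7.96 ± 0.79), the collagens col-14 (-7.62 ± 1.25) and col-97 (-7.57 ± 0.97), and pud-3 (-7.57 ± 0.83). idpc-6 fell from 407 summed counts to 1. Members of the abu, nsp and collagen families resemble each other in sequence, so their counts are uncertain.

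Ribosomal protein genes rose together in N2 from 6 to 72 h, whereas translation factor genes went both ways. Of 80 tested cytosolic ribosomal protein genes, 79 rose and 0 fell, also when adjusted over the list alone. Their mean lay 1.44 above that of other genes (camera adjusted p = 2.18e-29, and adjusted p = 0.797 with an estimated correlation). The estimated correlation called none of the 324 tests, so its lack of a call decides nothing here or for the lists below. Of the list members, which were matched by gene symbol alone, rpl-24.2 rose by 2.27 ± 0.16 and rpl-12 by 1.42 ± 0.13. Of 40 translation factor genes, 18 rose and 12 fell (19 and 12 adjusted over the list alone; camera adjusted p = 0.000366, and adjusted p = 0.797 with an estimated correlation). The initiation factor 3 genes eif-3.B (2.68 ± 0.18) and eif-3.G (2.16 ± 0.13) rose. The plain mean of the translation factor list was 0.27, but -0.25 with library size alone and -0.10 under ERCC scaling; relative to the median gene it was 0.38 and 0.47 there. Neuropeptide genes, which encode secreted signals of neurons, also rose, with 72 of 100 higher and 13 lower (73 and 13 adjusted over the list alone). Their mean lay 1.24 above other genes (camera adjusted p = 3.04e-10, and adjusted p = 0.611 with an estimated correlation), and examples were nlp-80 (2.87 ± 0.20) and flp-9 (2.33 ± 0.20).

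Genes of the cuticle, epidermis and muscle fell in N2 over the same interval. Of 130 cuticle collagen and collagen-processing genes, 76 fell and 12 rose, over all genes and adjusted over the list alone. The list mean lay at -1.75 relative to other genes (camera adjusted p = 5.87e-08, and adjusted p = 0.611 with an estimated correlation). col-166 fell by 5.87 ± 0.32 and col-180 by 5.84 ± 0.39. Of 27 genes of molting and developmental timing, 18 fell and 1 rose (19 and 1 adjusted over the list alone). The list mean lay at -1.52 (camera adjusted p = 0.00511, and adjusted p = 0.797 with an estimated correlation). blmp-1, a transcription factor of the molting programme, fell by 2.25 ± 0.20, whereas lin-28, a timing gene, rose by 1.22 ± 0.14. Hypodermis and seam markers had 13 of 21 lower and 0 higher (14 and 0 adjusted over the list alone; mean -1.86, camera adjusted p = 0.000981, and adjusted p = 0.611 with an estimated correlation). Body wall and pharyngeal muscle genes had 19 of 30 lower and 2 higher (19 and 2 adjusted over the list alone; mean -0.70, camera adjusted p = 8.37e-05, and adjusted p = 0.797 with an estimated correlation). dim-1, a muscle attachment gene, fell by 2.89 ± 0.29. Among 43 genes of the cell cycle and DNA replication, 18 fell, such as the cyclin D gene cyd-1 (-1.45 ± 0.21), and 1 rose (18 and 1 adjusted over the list alone; mean -0.44, camera adjusted p = 0.0254, and adjusted p = 0.978 with an estimated correlation).

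**Figure D3:**
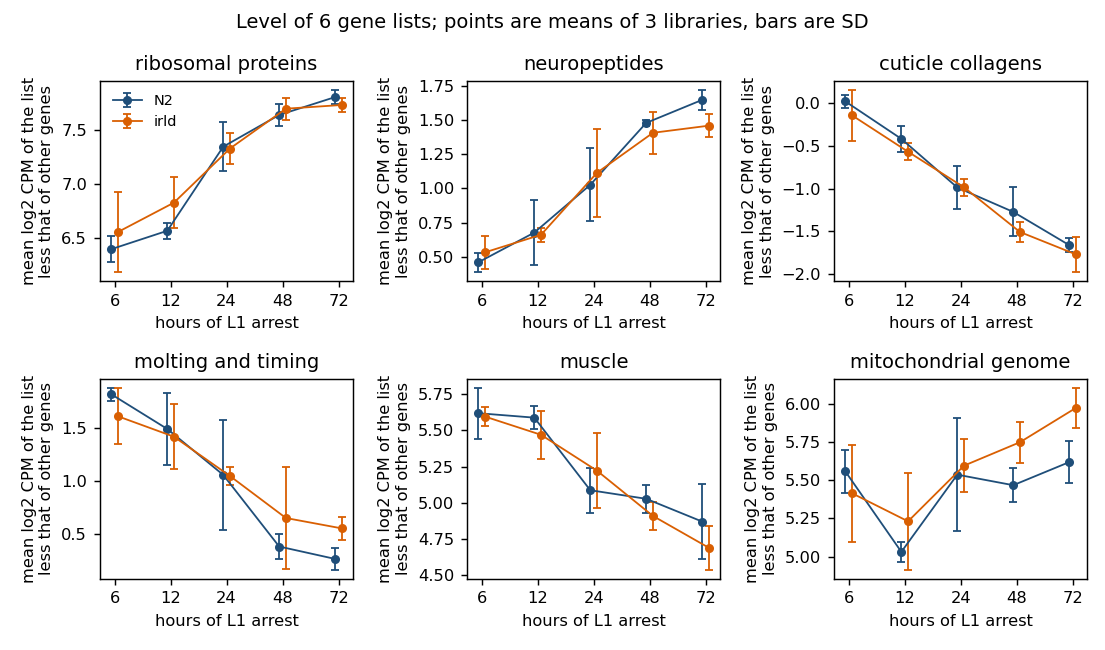
Mean log2 CPM of a gene list less that of the other tested genes (vertical axes) at each time of arrest (horizontal axes) for 6 lists in N2 (blue) and irld (orange). Points are means of 3 libraries and bars are SD; ribosomal protein and neuropeptide lists climbed and collagen, molting and muscle lists declined in both strains, from 6.40 to 7.81 for ribosomal proteins and from 0.021 to -1.66 for collagens in N2 between 6 and 72 h.

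Insulin-related lists moved in part. In N2, 13 of 37 DAF-16-activated genes rose and 9 fell from 6 to 72 h (13 and 9 adjusted over the list alone; mean 0.88 relative to other genes, camera adjusted p = 0.0992). Besides hsp-12.6, cyp-34A9, a cytochrome P450 gene, rose by 2.06 ± 0.23 and hil-1, a linker histone gene, by 2.14 ± 0.26. Of 15 DAF-16-repressed genes, 0 rose and 5 fell (0 and 4 adjusted over the list alone; mean -1.37, camera adjusted p = 0.207), among them dod-19 (-5.74 ± 0.51). Insulin pathway components had 13 of 29 higher and 4 lower (14 and 4 adjusted over the list alone; camera adjusted p = 0.202), with ist-1, an insulin receptor substrate gene, at 1.52 ± 0.27. Insulin-like peptides had 4 of 23 higher and 3 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.50), such as ins-17 (1.88 ± 0.18) and ins-4 (-3.20 ± 0.70). In the receptor L-domain family, 19 of 57 genes were expressed enough to be tested; 6 rose and 0 fell in N2 (4 and 0 adjusted over the list alone; mean 1.39, camera adjusted p = 0.140), led by irld-27 (2.52 ± 0.33) and irld-49 (2.43 ± 0.65).

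The mutant went through a similar course. In irld, 673 genes differed from 6 h at 12 h (297 higher and 376 lower), 4747 at 24 h (2191 and 2556), 6511 at 48 h (2800 and 3711) and 7223 at 72 h (3193 and 4030). Of those at 72 h, 1772 were at least 2-fold higher and 2828 at least 2-fold lower. The test over all times called 6680 genes. The largest rises were those of nspc-10 (7.28 ± 0.71), fat-6 (5.51 ± 0.59, from 25.7 ± 18.1 to 1169 ± 28 CPM), nspc-9 (5.42 ± 0.54), hsp-12.6 (5.36 ± 0.50) and sre-12 (5.24 ± 0.82). The largest falls were those of grl-21 (-8.85 ± 1.08), chtb-3 (-7.86 ± 0.81), abu-10 (-7.37 ± 0.64) and abu-8 (-7.13 ± 0.64), with pud-3, which had 1327 summed counts at 6 h and 3 at 72 h. icl-1 changed by -3.52 ± 0.86. Ribosomal protein genes had 79 of 80 higher and 0 lower, and neuropeptide genes 62 of 100 higher and 11 lower. Collagen genes had 76 of 130 lower and 11 higher, and muscle genes 22 of 30 lower and 2 higher. Relative to other genes the ribosomal and neuropeptide means were 1.2 and 0.97 in irld. Their plain means of 0.91 and 0.69 were -0.68 and -0.85 under ERCC scaling, but 0.91 and 0.73 relative to the median gene there.

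Counts in irld also depended on libraries and scaling. The 12 h count was 1456, 141 or 458 without the irld 6 h library numbered 1, 3 or 2. It was 188 or 324 without the irld 12 h library numbered 1 or 2, and 0 when the 6 libraries compared were fitted alone. It was higher with the replicate number as a block and by DESeq2, as given below. Without all libraries numbered 2 the counts at 12, 24, 48 and 72 h were 6, 1976, 3530 and 4474. The share of higher calls was 44.1%, 46.2%, 43% and 44.2% at 12, 24, 48 and 72 h. Upper quartile scaling gave 61.3% at 12 h and library size alone 33.4%, 26%, 21.1% and 21%. ERCC scaling gave 0 calls at 12 h, then 1.93%, 0.75% and 1.46% of 1037, 4815 and 3485 calls, with the median gene at -1.58 at 72 h.

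The changes from 6 to 72 h were similar in both strains across genes. Over 15508 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.917 and Spearman's rho 0.916. The slope of irld on N2 was 0.82 and that of N2 on irld 1.02. Both strains called 2853 genes higher, where independent lists of these sizes would share 739, and 3503 lower, where they would share 1125. No gene was called in opposite directions, 1563 genes were called in N2 alone and 867 in irld alone. Of the genes called in N2, 99.4% had the same sign in irld. The test of the difference itself called 0 genes, as given above.

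**Figure D4:**
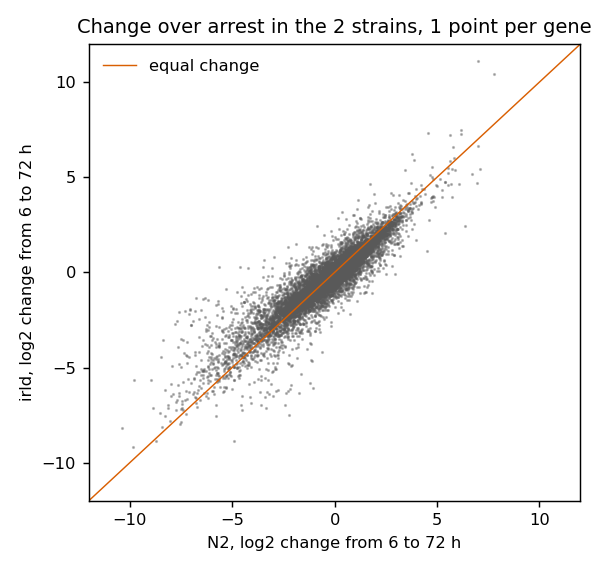
Log2 change from 6 to 72 h of arrest in irld (vertical axis) against that in N2 (horizontal axis), with 1 point for each of 15508 genes and a line of equal change. Points gather along the line (Pearson's r 0.917 across genes).

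Each library's place along the N2 course was scored as the mean log2 CPM of genes higher at 72 h less that of genes lower at 72 h. The score rose in N2 from -0.30 ± 0.04 (SD, n = 3) at 6 h to 2.90 ± 0.17 at 72 h, the times that define it. At 12, 24 and 48 h it was 0.57 ± 0.21, 1.83 ± 0.45 and 2.49 ± 0.24 in N2 and 0.81 ± 0.36, 1.87 ± 0.09 and 2.48 ± 0.28 in irld. Averaged over these 3 times, irld less N2 was 0.09 (exact permutation of strain labels within time, two-sided, p = 0.508, 8000 splits).

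Shares of counts in each library were compared between strains by exact permutation within time, two-sided, with adjustment over 5 measures. The ERCC spike-in took 1.92% of counts in N2 and 1.93% in irld on average (adjusted p = 0.994), total counts differed by 7363 (adjusted p = 0.994), and the 10 most abundant genes took 12.5% and 11.9% (adjusted p = 0.361). Of the 5, the mitochondrial and ribosomal RNA measures were added after the data had been seen. Genes of the mitochondrial genome took 1.54% in N2 and 1.71% in irld (permutation p = 0.00897, adjusted p = 0.0448), but the adjusted p was 0.332 without the libraries numbered 1 and 0.0919 without those numbered 3. At 48 h the 3 irld libraries lay above the 3 N2 libraries (1.58% ± 0.07 and 1.32% ± 0.06, n = 3), as at 72 h (1.67% ± 0.25 and 1.27% ± 0.08). At 6 h the irld mean was the lower one (1.95% ± 0.22 and 2.05% ± 0.11), and the libraries of both strains overlapped at 6, 12 and 24 h. Chance gives no overlap in this direction or the other in 10% of groups of 3 against 3. Ribosomal RNA genes took 4.0% in N2 and 2.87% in irld (permutation p = 0.0248, adjusted p = 0.0621). With labels exchanged only within time and replicate number the adjusted p was 0.0278. The 3 irld libraries lay below the 3 N2 libraries at 72 h (3.08% ± 0.97 and 4.72% ± 0.67) and overlapped with them at the other times.

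**Figure D5:**
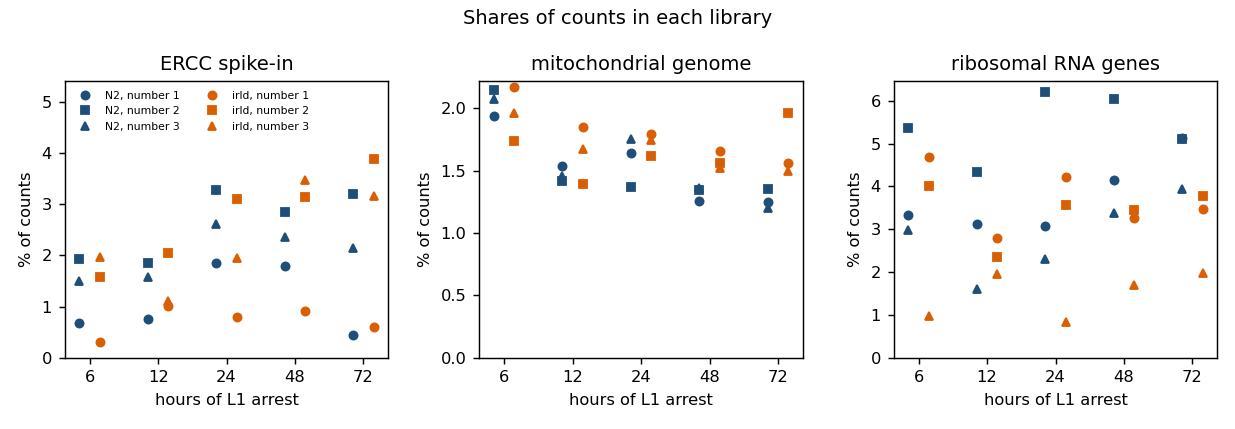
Percent of counts (vertical axes, from 0) on the ERCC spike-in, genes of the mitochondrial genome and ribosomal RNA genes at each time of arrest (horizontal axes). Each point is 1 library, coloured by strain (N2 blue, irld orange) with a marker for its replicate number; at 72 h the irld libraries averaged 1.67% mitochondrial counts and the N2 libraries 1.27%.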

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

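All tests of the mitochondrial pattern, the ribosomal test with an estimated correlation, the permutation of lists and the count of position scores by number were chosen after the results were seen; the other ribosomal tests and the splits were written before their values were computed. The results here were singled out because the change of a gene list from 6 to 72 h differed between the strains by camera with a preset correlation. Relative to other genes, irld less N2 was -0.24 for ribosomal protein genes, 0.49 for molting and timing genes, -0.27 for neuropeptide genes and 0.53 for genes of the mitochondrial genome. Their camera adjusted p was 2.06e-09, 0.00277, 0.000182 and 1.70e-10. The adjusted p was 0.978, 0.797, 0.817 and 0.611 with an estimated correlation, a setting that called no list in any comparison. By exact permutation, unadjusted p was 0.37, 0.015, 0.05 and 0.07, and none passed adjustment over 72 tests (lowest 0.936). The 400 splits of this test cannot give a p small enough for a single list to pass that adjustment. The lack of a call therefore decides nothing for these lists. Ribosomal and neuropeptide genes rose and molting genes fell in both strains.

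Splits of the strain labels within time were used to ask how often lists are called by chance. The real labels gave 39 called strain tests, and 90 of 100 splits, the real one included, gave as many or more, with a median of 52 in the other splits and a highest of 86. Chance cannot be excluded for the list calls between strains.

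Ribosomal protein genes lay higher in irld at 6 and 12 h, by 0.15 and 0.26 relative to other genes. Without the libraries numbered 1 the mean log2 difference of the list at 6 h went from 0.17 to -0.09 and at 12 h from 0.24 to 0.07, so that at most 0.31 of it was left. With an estimated correlation the smaller unadjusted camera p of both times was 0.0565. Relative to other genes, the irld libraries all lay above the N2 libraries at 1 of the 2 times (12 h), but by the list mean itself the strains overlapped at both. The libraries numbered 1 lay further along the course, with the highest position score in 10 of 10 groups, by 0.068 to 0.86 above the mean of the others. Each group holds 1 such library, so their place alone would not set the strains apart. The irld library numbered 1 scored 0.57 at 6 h and the N2 one -0.25, and at 12 h 1.22 and 0.80. Without the irld 6 h library numbered 1 and the N2 24 h library numbered 2, the 6 h difference relative to other genes was -0.05. The 6 h difference thus depended on that irld library. The further place of the irld libraries numbered 1 and genes that move as 1 block both remain open as explanations. A strain difference at 12 h cannot be told apart from them with 3 libraries per group.

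Genes of the mitochondrial genome lay higher in irld at 48 h (11 of 12) and 72 h (12 of 12, log2 0.23 to 0.84, 6 at an unadjusted p under 0.05 and 0 called). Weaker poly(A) selection in irld would raise ribosomal RNA too, but its share was lower in irld at both times, with the smaller gap at -1.65 percentage points. That share is a rough gauge of selection. The alignment dropped reads of many-copy genes, and ribosomal RNA genes of the mitochondrial genome were not set apart. The delay tested was one that would put the irld 72 h libraries no further along the course than N2 at 24 h. The lowest of them lay 0.74 units of the position score beyond the N2 24 h mean. A smaller delay was not tested. At 72 h the irld libraries averaged 2.72 ± 0.14 against 2.90 ± 0.17 in N2, whose 72 h libraries helped to define the score. With an estimated correlation the larger unadjusted p of both times was 0.0617, so that genes moving as 1 block cannot be told apart from a shared shift at 48 h, with 3 libraries per group. A strain difference in mitochondrial transcripts late in arrest stays open as a hypothesis, found and tested on the same data.

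At 24 h, camera with a preset correlation also called lists lower in irld: proteasome subunits (-0.16), cell cycle genes (-0.33), histone genes (-0.39) and embryo genes (-0.54), with adjusted p of 0.797, 0.977, 0.977 and 0.977 with an estimated correlation. Those of histone, cell cycle and embryo genes depended on which libraries were used: without the 2 libraries away from their groups (added after the data had been seen), of which the N2 24 h one is number 2, the histone difference was 0.035. Without number 3 the cell cycle and embryo differences were -0.041 and 0.083. Proteasome subunits ranged from -0.10 to -0.22 with each number left out.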

How the results depend on the processing

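No strain comparison of genes gained more than 7 calls under any alternative run. ERCC scaling gave 1 call at 24 h, 1 for the strain mean and 1 for the interaction. Leaving out libraries gave 0 to 1 at 24 h and 0 to 7 for the mean (7 without number 1, 3 without number 3). The other strain results had 0 calls under every alternative. The position score ranged from -0.01 (without number 2) to 0.18 (without number 3), with exact permutation p of 0.316 to 0.935.

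ERCC scaling gave 0, 2134, 3213 and 1873 calls in N2 at 12, 24, 48 and 72 h, and 0, 1037, 4815 and 3485 in irld. The tests over all times gave 3033 and 3266. Under it daf-2, daf-16 and mtl-1 in irld at 72 h turned to -0.62, -0.67 and -0.89, which is still 0.96, 0.91 and 0.69 above the median gene (-1.58), as the scaling lowers all genes. Spike-in shares ranged from 0.304% to 3.88% of counts between libraries. Fitting the compared groups alone gave 1579 (N2, 12 h), 0 (irld, 12 h) and 2857 (irld, 24 h). The irld 12 h count was 423 with no filter and 1091 by DESeq2. For these the cause was not tested.

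With libraries left out, which lowers the number of samples, N2 gave 1 to 1349 calls at 12 h, 3511 to 5822 at 24 h, 4714 to 7412 at 48 h, 5669 to 8177 at 72 h and 4614 to 8114 over all times. irld gave 6 to 1699, 1976 to 5637, 3530 to 6992, 4474 to 7591 and 3152 to 7053. The low ends came from leaving out 10 libraries with 1 number, mostly number 2. Without the 2 libraries away from their groups, which was added after the data had been seen, irld at 12 h gave 1699.

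The labels do not say what a replicate number shares, and 6 of 15 pairs of same-numbered libraries correlated above 0.1 (-0.16 to 0.30). The main tests therefore left the number out. Libraries of the same number in any group correlated by 0.131 on average (0.236 for number 1). Those of other numbers gave -0.065, which largely follows from it, since deviations within a group sum to 0. Of 15, 6 correlated best with their own number. The position score was highest in number 1 in 10 of 10 groups. The mean ribosomal RNA share also varied by number (3.73%, 4.42% and 2.17% for numbers 1, 2 and 3), as did the median ERCC share (0.774%, 2.97% and 2.05%). In every group, number 1 had the lowest ERCC share and number 3 the lowest ribosomal RNA share. Levels shared by number were thus present. The main tests leave this shared variation in the spread of the libraries. With the number as a block, 12 h gave 1550 calls in N2 and 1157 in irld, 72 h gave 8381 in N2, and strain comparisons of genes gave 0. For the ribosomal RNA share (-1.13 percentage points) the block changed the adjusted p from 0.0621 to 0.0278; no other library measure changed its call under it. The mitochondrial share difference ranged from 0.119 (without number 1) to 0.204 percentage points (without number 3), with adjusted p of 0.332 and 0.0919 there and 0.00772 without number 2; these alternatives were added after the data had been seen.

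List calls numbered 56, against 0 with an estimated correlation, 41 by fry and 53 to 78 with libraries left out. The 56 held 39 between strains and 17 over time, whereas all 41 by fry were over time. Of 39 called list results between strains, 13 turned in the sign of the relative mean or in camera direction, and of 17 over time 0 did. With libraries left out the ribosomal list ranged from -0.13 to 0.29 at 6 h (-0.05 without the 2 libraries) and from -0.025 to 0.18 for the mean. Collagens ranged from -0.21 to 0.046 at 6 h (0.03 without the 2 libraries), histones from -0.46 to 0.19 for the mean, mitochondrial genes from -0.37 to 0.075 at 6 h, embryo genes from -1.1 to 0.083 at 24 h and neurons from 0.0050 to 0.37 at 24 h. Histones ranged from -0.63 to 0.051 at 24 h (0.035 without the 2 libraries), lipolysis from -0.37 to 0.024 at 6 h, receptor L-domain genes from -0.028 to 0.67 at 12 h, TGF-beta and steroid hormone genes from -0.022 to 0.35 at 24 h, molting genes from -0.021 to 0.58 at 48 h and muscle from -0.13 to 0.0098 for the mean. Of 3608 values of called named genes under alternatives, 3481 kept direction and call, 124 kept direction alone and 3 turned. Of those that kept both, 1701 came from leaving out libraries, which changes the fit little. Under ERCC scaling, 73 of 172 values kept both, 96 kept direction alone and 3 turned. The precision given for strain comparisons holds for genes with a mean CPM of at least 2.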

Other observations

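The spike-in test by series of strain and replicate number and the tests of library measures at 72 against 6 h were chosen after the result was seen; the test of depth and the splits were written before their values were computed. Metabolic and stress genes moved in both directions in N2 from 6 to 72 h, and no list in this paragraph and the next passed camera there. Fatty acid synthesis, desaturation and elongation had 10 of 22 genes higher and 6 lower (10 and 6 adjusted over the list alone; adjusted p = 0.425). fat-2, a desaturase gene, rose by 2.77 ± 0.17, whereas fasn-1, the fatty acid synthase gene, fell by 2.81 ± 0.35. Lipolysis and fatty acid oxidation had 5 of 33 higher and 19 lower (5 and 19; adjusted p = 0.0702), with kat-1, a thiolase gene, at -1.2 ± 0.15. Glyoxylate cycle, gluconeogenesis and trehalose genes had 5 of 18 higher and 10 lower (5 and 11; adjusted p = 0.314), with fbp-1, fructose bisphosphatase, at -1.84 ± 0.17. Glycolysis had 4 of 21 higher and 7 lower (4 and 7; adjusted p = 0.629). Mitochondrial respiration and the TCA cycle had 14 of 46 higher and 13 lower (14 and 14; adjusted p = 0.944), with mdh-2, malate dehydrogenase, at -1.75 ± 0.17. Heat-shock proteins had 9 of 28 higher and 6 lower (9 and 6; adjusted p = 0.418), with hsp-6, a mitochondrial chaperone, at 2.03 ± 0.15. Oxidative stress and detoxification genes had 6 of 29 higher and 12 lower (6 and 12; adjusted p = 0.583), cytochrome P450 genes 9 of 64 and 17 (9 and 15; adjusted p = 0.789), and UDP-glycosyltransferase genes 8 of 57 and 22 (8 and 22; adjusted p = 0.166). Autophagy and lysosome genes had 16 of 39 higher and 4 lower (16 and 4; adjusted p = 0.0511), with the autophagy gene epg-6 at 1.46 ± 0.13. In irld they had 15 and 4 (15 and 4; adjusted p = 0.0474, and adjusted p = 0.977 with an estimated correlation). Their mean turned to -0.23 in N2 and -0.20 in irld with library size alone, and stayed 0.39 above the median gene in both. Proteasome subunits had 10 of 33 higher and 1 lower (8 and 0; adjusted p = 0.197).

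Signalling, immunity and tissue lists were also mixed in N2 from 6 to 72 h. Nutrient sensing genes had 6 of 21 higher and 4 lower (6 and 4 adjusted over the list alone; adjusted p = 0.423), with aak-1, an AMP-activated kinase subunit gene, at 3.01 ± 0.23. TGF-beta and steroid hormone genes had 7 of 25 higher and 6 lower (7 and 6; adjusted p = 0.876), with daf-7, a TGF-beta ligand gene, at 2.67 ± 0.62. Innate immunity effectors had 31 of 185 higher and 75 lower (31 and 76; adjusted p = 0.0513), with lys-1, a lysozyme gene, at -3.36 ± 0.27. Nuclear hormone receptors had 61 of 208 higher and 54 lower (63 and 58; adjusted p = 0.510), chemoreceptors 77 of 316 and 56 (74 and 52; adjusted p = 0.407), and histone genes 5 of 33 and 3 (5 and 2; adjusted p = 0.510). Intestinal markers had 5 of 22 higher and 12 lower (5 and 12; adjusted p = 0.190), with the intestinal actin gene act-5 at -4.07 ± 0.42. Neuron markers had 11 of 34 higher and 12 lower (11 and 12; adjusted p = 0.901), with the peptide-processing genes egl-21 (2.00 ± 0.17) and egl-3 (2.07 ± 0.22) higher. Genes of the mitochondrial genome had 0 of 12 higher and 2 lower (0 and 2; adjusted p = 0.629). Lists of sperm, adult, embryo and germline genes had few calls: 1 of 42 sperm genes was expressed enough to be tested and was not called. Adult yolk and egg genes had 1 of 17 higher and 1 lower (1 and 1; adjusted p = 0.593), embryo genes 2 of 23 and 4 (2 and 4; adjusted p = 0.811), and germline genes 3 of 25 and 2 (2 and 2; adjusted p = 0.869). The mean, the mean relative to other genes, the median and the camera direction did not all agree in sign for the fatty acid synthesis, glycolysis, mitochondrial respiration, TGF-beta and steroid hormone, nuclear hormone receptor, neuron and mitochondrial genome lists.

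The ERCC share of counts was higher at 72 than at 6 h by 0.915 percentage points on average (exact permutation within strain, two-sided, p = 0.185, adjusted p = 0.231 over 5 measures). Of the other measures, the 10 most abundant genes took 4.73 percentage points more at 72 h (adjusted p = 0.025) and genes of the mitochondrial genome 0.535 less (adjusted p = 0.0375). The mitochondrial change was -0.788 in N2 and -0.282 in irld. Total counts and the ribosomal RNA share did not pass (adjusted p = 0.231 and 0.64). The 72 h to 6 h ratio was above 1 in 5 of 6 series of strain and replicate number, the exception being N2 number 1 (0.655). Libraries numbered 1 had a lower median share (0.774%) than those numbered 2 (2.97%) and 3 (2.05%). In every group the library numbered 1 had the lowest ERCC share, so the level went with the number. The labels do not say whether each number was prepared as its own batch. As an explanation of the higher late share, such batches stay open, since that change lay within the spread of the libraries. That spread includes the differences between numbers, which the permutation did not remove. Depth was not related to it, with a Spearman correlation of 0.0790 over 30 libraries. No biological explanation was tested, since the spike-in was added per amount of total RNA.

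Other splits of the libraries were fitted for each comparison. For irld against N2 at 6, 12, 24, 48 and 72 h, there were 10 splits of 3 against 3 each, and all 10 gave at least the real 0 calls, with a highest other of 15 at 6 h and 0 at the other times; 10 splits are too few for a share under 0.05. For the strain mean, the interaction and the difference of changes, all 100 splits gave at least the real 0, with a highest other of 6, 28 and 3. Since any split gives at least 0 calls, the splits say nothing about chance where the real count was 0. For N2 at 12, 24, 48 and 72 h against 6 h, 1 of 10 splits, the real one, gave 963, 5296, 7070 and 7919 calls, with 0 in all others. For irld the real split gave 673, 4747, 6511 and 7223, with a highest other of 410, 65, 0 and 1; these 10 splits are also too few. Over all times, 1 of 50 splits, the real one, gave as many as the real 7686 in N2 and 6680 in irld, with a highest other of 4573 and 3982. Of the other splits, 13 in N2 and 23 in irld gave any calls. Chance is thus unlikely for both, although 50 splits cannot show a share below 1 in 50.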
